A study of Rattus norvegicus with 16 samples.

How the data were processed

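Placental RNA of 16 Sprague-Dawley rat fetuses was sequenced, 4 in each of the saline male, PolyI:C male, saline female and PolyI:C female groups, which were taken from the sample labels. The dam of each placenta was inferred from the sample codes, whose first part is shared by 1 male and 1 female placenta of a treatment. This gave 8 dams, 4 per treatment, and the design text also gives 1 male and 1 female placenta per rat. Poly(A) RNA was made into libraries with a directional kit and sequenced as paired-end reads, per the labels' protocols. Reads were aligned with STAR 2.7.3a to the rat build rn7 in the Partek software, and DESeq2 is named among the tools, per the submitters' processing notes. Whether reads were counted by strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

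The deposited table gives 1 value per gene and library, a signal that is never negative and equals estimated read counts divided by 1 size factor per library. This was read from the values themselves, whose low end steps in multiples of what 1 read is worth, 0.820 to 1.39 depending on the library. Between 91.0% and 92.1% of the values under 2000 reads were whole within 0.1 read, so the remaining values are not whole reads and no count model was used. The table has 14951 genes, all with a value above 0 in every library, and the lowest maximum of a gene over the libraries was 19.7, so genes of lower expression were not analysed here. Of the gene names, 12660 matched a symbol and 275 an older symbol in a reference gene table of the assembly GRCr8, which was used for names alone because the build differs, and 1965 were Ensembl or clone identifiers. In 4 sets of genes, 10 genes in all, the values were identical in every library. Reads shared within the Gbp, Ifit, Oas, Mx, RT1, Prl, Psg and Ceacam families could be divided among members by the counting, so values of single members are uncertain.

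Depth was estimated as the sum of the values over the value of 1 read and was 21.2 to 33.6 M reads per library. Over all genes the spread between placentas was larger than counting error: the chi-square per degree of freedom between libraries of a group was 38.3 to 201, so no 2 libraries were copies of each other. Counting error weighs more in genes of few reads, such as Cxcl11 in saline placentas. Same-numbered placentas of a treatment share a dam, as inferred from the sample codes. Their deviations from the group means correlated by 0.0814 on average over 8 pairs (-0.210 to 0.296), and by -0.0248 over 24 pairs of different dams. Deviations sum to 0 within a group, so the second value largely follows from the first and is no control. The dam as a block was the alternative in the comparisons of males with females and in the interaction, whose main analysis had no block. Across treatments the numbers only name placentas.

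A test of raw counts was chosen before the data were examined, as were the samples of each comparison, the gene lists and the rule for named genes. Because the values turned out not to be counts, limma 3.58.1 (R 4.3.3) with a mean-variance trend was used in its place on log2(value + 1), so fold changes are on that scale and understate changes of low genes. Genes with a value of at least 10 in at least 4 of the fitted libraries were tested, and an adjusted p (Benjamini-Hochberg) under 0.05 was taken as passing. All tests are two-sided. PolyI:C was compared with saline within males, within females and per dam, males with females within each treatment, and the interaction of sex and treatment was fitted over all 16 placentas. The comparison per dam used the mean of the 2 deposited values of a dam, where summed counts had been planned. In the interaction, placentas of a dam were treated as separate samples.

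The 30 gene lists were antiviral interferon-stimulated genes, interferon signalling and viral RNA sensing, guanylate-binding proteins and immunity-related GTPases, antigen processing and MHC class I, MHC class II, chemokines, inflammatory cytokines and NF-kB targets, complement and coagulation, angiogenesis and vascular tone, hypoxia and glycolysis, nutrient, ion and drug transport, steroid and prostaglandin metabolism, markers of junctional zone trophoblast, labyrinth trophoblast, decidua and smooth muscle, yolk sac with amnion and epithelium, endothelium and pericytes, macrophages and monocytes, neutrophils, natural killer and T cells, B cells and erythroid cells, immediate early and heat shock genes, glucocorticoid-responsive genes, cell cycle, extracellular matrix, cell death, unfolded protein response and amino acid stress, mitochondrially encoded genes and sex-linked genes. Some genes belong to more than 1 list, such as Tnfsf10, Angptl4, Lcn2 and Mmp9. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison.

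The named genes followed a rule: for each sex the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, up to 4 members of each list with the smallest p, the 10 smallest p for the interaction and for each comparison of males with females, and the same genes per dam. Genes with no symbol were skipped in the ranking, including clone identifiers, which the rule had not listed. The text names a subset of the genes the rule gives, and further list members past the threshold where a count was small, chosen after their values were seen.

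Alternatives were no filter, a filter at 1 CPM in 4 libraries, limma-voom 3.58.1 on the estimated reads, all placentas in 1 fit, the replicate number or dam as a block, trimmed mean of M values or library totals for scaling, pseudocounts of 0.5 and 10, limma without a trend, a fold threshold, and leaving out each library or dam. Random dam effects used statmod 1.5.0. Each count of genes was also computed for all 35 splits of the placentas or dams compared into groups of 4. The 2 scalings, the pseudocounts, the fit without a trend and the junctional zone level as a covariate were added after the data were seen. Count models that had been listed as further alternatives were not run because the values are not counts. Fits were tested on simulated values with 100 genes changed 2-fold and 100 changed 4-fold. In males 65% of 2-fold and 97% of 4-fold changes were recovered over 14830 genes, in females 69% and 97% over 14836, per dam 92% and 100% over 14870, in the interaction 44% and 89% over 14940, and between the sexes 61% and 95% in saline over 14843 and 72% and 89% in PolyI:C placentas over 14833. False calls numbered 3 to 9. The changed list was found in every comparison, and 0 of 29 unchanged lists passed in camera with the preset correlation. The simulated genes and libraries were drawn independently of each other, with no effect of the dam. The changed genes were drawn only from genes with a mean value above a floor higher than the filter's value of 10. These figures therefore do not cover genes of low values, correlated genes or placentas that share a dam. They also cannot test whether the preset correlation is adequate. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.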

Results

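RNA sequencing was carried out on 16 placentas of Sprague-Dawley rats, taken on gestational day 18.5, 5 h after the dam had received saline or 4 mg/kg PolyI:C into a vein. PolyI:C is a synthetic double-stranded RNA that cells sense as viral RNA, and its injection into pregnant rodents is a model of maternal immune activation by a virus. The 4 groups, saline male, PolyI:C male, saline female and PolyI:C female, held 4 placentas each. Each of the 4 dams per treatment gave 1 male and 1 female placenta, and placentas of a treatment with the same number shared a dam. The table held 14951 genes as normalised read counts, with gene names and no genome positions. Estimated depth ranged from 21.2 to 33.6 M reads per library, with group means of 29.03 ± 5.40 M in saline males, 30.5 ± 2.17 M in PolyI:C males, 25.5 ± 2.60 M in saline females and 28.7 ± 1.40 M in PolyI:C females (SD, n = 4 each).

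The first comparison asked which genes responded to PolyI:C in male placentas. Chemokines that attract T cells and interferon-induced GTPases had the largest rises among genes with a symbol and separate groups. Cxcl11, a ligand of the chemokine receptor CXCR3, went from 4.47 ± 3.52 to 293 ± 134 normalised reads (SD, n = 4 each), a log2 fold change of 5.83 ± 0.52 (SE, limma adjusted p = 0.000402). Cxcl10, another CXCR3 ligand, went from 37.6 ± 13.9 to 1204 ± 299.8, a log2 fold change of 5.01 ± 0.29 (limma adjusted p = 2.45e-05). Gbp5, a guanylate-binding protein that acts in inflammasome assembly, went from 39.4 ± 15.5 to 753.5 ± 116, a log2 fold change of 4.28 ± 0.25 (limma adjusted p = 2.45e-05). Mx1, an antiviral GTPase, went from 143 ± 35.1 to 2064 ± 899.6, a log2 fold change of 3.76 ± 0.30 (limma adjusted p = 0.000218). Gbp4 had a log2 fold change of 3.39, the death ligand Tnfsf10 of 3.37, Gbp2 of 3.21 and Mx2 of 3.10. The nuclear DNA-binding protein Mnda, at 3.04, and Ifit2, which binds viral RNA, at 2.94, completed the 10 largest rises.

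Of 14825 genes tested in male placentas, 81 passed an adjusted p of 0.05 in limma, of which 78 rose and 3 fell, and 74 of them changed at least 2-fold. The 3 falls were Dusp8, a phosphatase that acts on stress-activated kinases, and the unnamed genes ENSRNOG00000062337 and ENSRNOG00000065674, which were picked out after their values were seen. Dusp8 went from 355 ± 72.7 to 175 ± 9.55, a log2 fold change of -1.0 ± 0.18 (limma adjusted p = 0.0415). The unnamed genes held identical values in every library, so they stand for 1 measurement, with a log2 fold change of -3.63 ± 0.53 (limma adjusted p = 0.0104) and 28759 normalised reads in saline male 4 against 4160 to 5953 in the other saline males. An unadjusted p under 0.05 was reached by 1318 genes, and limma-voom called 74. The former number was reached by 6 of the 35 splits of these placentas into groups of 4, the real one included (highest other 2669). The count depended on single libraries. It was 34 without PolyI:C male 4, 42 without PolyI:C male 1 or PolyI:C male 3, 47 without saline male 2, 49 without saline male 3 and 130 without PolyI:C male 2. Of the 40 named genes past the threshold, 20 stayed past it whichever library was left out.

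**Figure D1:**
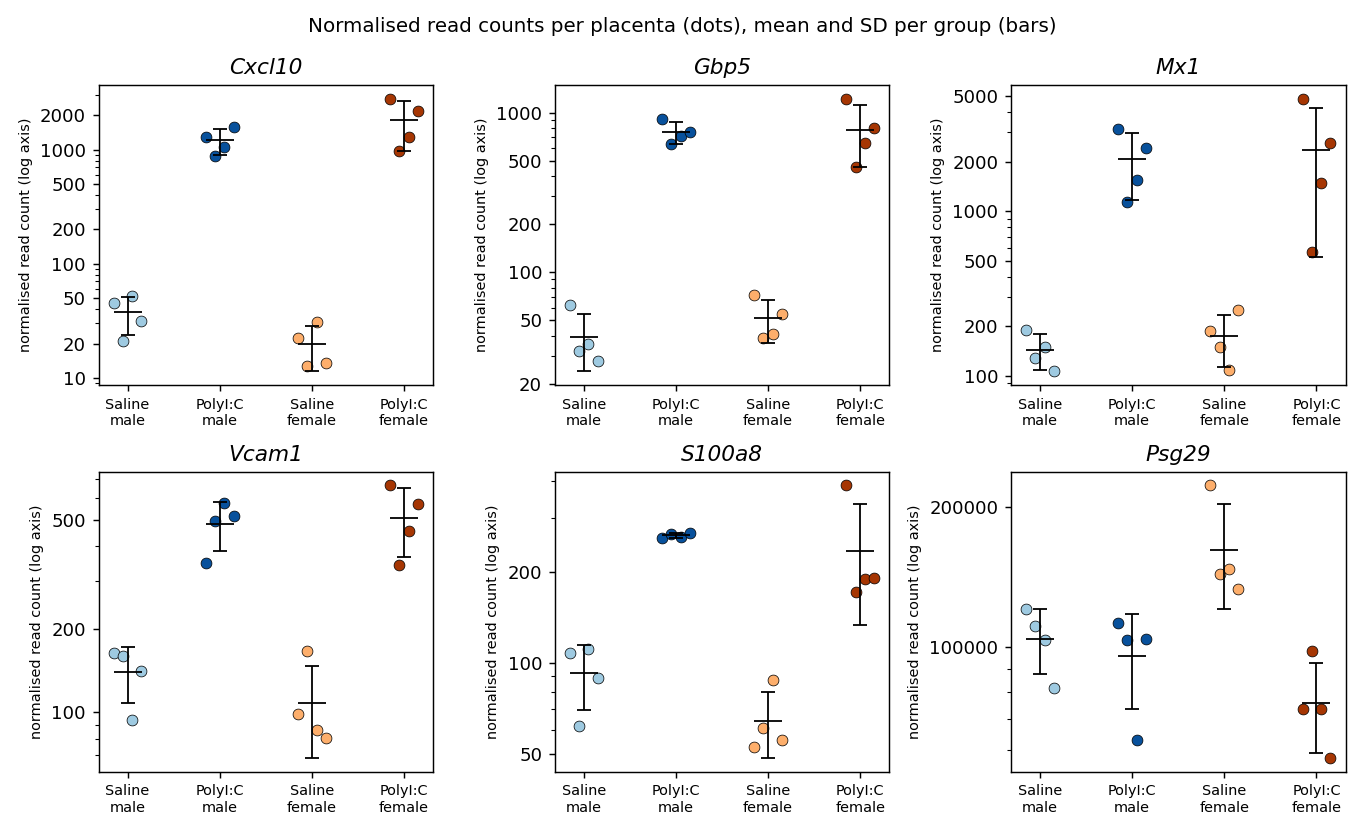
Normalised read counts on a log axis of Cxcl10, Gbp5, Mx1, Vcam1, S100a8 and Psg29 in the 4 groups, with a dot per placenta and the mean with its SD (n = 4). Cxcl10 went from 37.6 to 1204 in males and from 19.9 to 1803 in females, while Psg29 went from 161965 to 75749 in females.

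The antiviral interferon-stimulated genes, whose products block viral replication, rose in male placentas in 21 of 42 measured members, and no member fell. Adjusted over the list alone, 36 rose, and the list's median log2 fold change was 1.30. In camera, limma's test of a list against all other genes, the adjusted p was 2.06e-49 with a preset correlation of 0.01, and the adjusted p = 0.0260 with an estimated correlation. Among its members, Ifit2 went from 409 ± 116 to 3148 ± 917, Mx2 from 233 ± 63.1 to 2064 ± 707, and the ubiquitin ligase Herc6 had a log2 fold change of 2.697. Of 8 guanylate-binding proteins and immunity-related GTPases, which attack intracellular microbes, 7 rose and 1 did not pass, also adjusted over the list alone, with a median of 2.695 (camera adjusted p = 5.56e-24, and adjusted p = 0.0260 with an estimated correlation). Gbp2 went from 238 ± 73.0 to 2181 ± 504, and Gbp6 had a log2 fold change of 2.76.

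Interferon signalling and viral RNA sensing genes rose in 5 of 30 members in males and 25 did not pass. The interferon signalling list had a median of 0.51, and 15 rose adjusted over the list alone (camera adjusted p = 1.58e-13, and adjusted p = 0.0774 with an estimated correlation). The 5 were Zbp1, a sensor of Z-form nucleic acids, at a log2 fold change of 2.53, the antibody receptor Trim21 at 2.41, Ddx58, which encodes the RNA sensor RIG-I, at 2.08, Ifih1, which encodes the RNA sensor MDA5, at 1.89, and the transcription factor Irf9 at 1.00. None of 17 genes of antigen processing and MHC class I passed in males. The antigen processing list had a median of 0.46, and 9 rose adjusted over the list alone (camera adjusted p = 1.55e-09, and adjusted p = 0.128 with an estimated correlation). Psmb9, a subunit of the immunoproteasome, had a log2 fold change of 1.70 and the peptide transporter Tap1 of 1.80, at limma adjusted p values of 0.0816 and 0.0892, and saline male 4 lay apart in Tap1 at 404.4. None of 9 MHC class II genes passed. The MHC class II list had a median of -0.48, and 1 fell adjusted over the list alone (camera adjusted p = 0.0885).

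Of 18 measured chemokines, Cxcl9, Cxcl10 and Cxcl11 rose in males and 15 did not pass. The chemokine list had a median of 1.03, and 7 rose adjusted over the list alone (camera adjusted p = 7.55e-09, and adjusted p = 0.0260 with an estimated correlation). Of 33 inflammatory cytokines and NF-kB targets, Tnfsf10, the apoptosis inhibitor Birc3 and the leukocyte adhesion molecule Vcam1 rose and 30 did not pass, while 9 rose and 1 fell adjusted over the list alone. Birc3 had a log2 fold change of 2.11, and Vcam1 went from 140 ± 32.0 to 483 ± 97.2. The list's median was 0.52 (camera adjusted p = 8.04e-09, and adjusted p = 0.0913 with an estimated correlation). Of 25 cell death genes, Tnfsf10, the necroptosis effector Mlkl at 1.33 and the inflammatory caspase Casp4 at 1.21 (with saline male 4 apart at 64.0) rose and 22 did not pass. Adjusted over the list alone 9 cell death genes rose, and the median was 0.25 (camera adjusted p = 4.00e-06, and adjusted p = 0.0260 with an estimated correlation). PolyI:C male 1 lay apart in mean log2 level of the cell death list at 7.58, against 7.33 to 7.37 in the other PolyI:C males. Complement and coagulation genes passed in 1 of 33 members, the complement protease C1s at a log2 fold change of 1.48. The complement list had a median of 0.11, and 2 rose adjusted over the list alone (camera adjusted p = 0.00619, and adjusted p = 0.234 with an estimated correlation).

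Neutrophil markers rose in males in 3 of 11 members and 8 did not pass. The neutrophil list had a median of 0.79, and 6 rose adjusted over the list alone (camera adjusted p = 1.28e-06, and adjusted p = 0.0836 with an estimated correlation). They were the collagenase Mmp8, from 28.9 ± 8.52 to 120.2 ± 19.5, and the calprotectin genes S100a8, from 92.2 ± 22.5 to 264 ± 4.75, and S100a9, from 296 ± 57.9 to 666 ± 76.1. Of 21 macrophage and monocyte markers, the antibody receptor Fcgr3a rose at a log2 fold change of 2.55 and 20 did not pass. The macrophage list had a median of 0.29, and 2 rose adjusted over the list alone (camera adjusted p = 0.000575, and adjusted p = 0.191 with an estimated correlation). Saline male 4 lay apart in the mean log2 level of this list at 6.22, against 6.74 to 6.81 in the other saline males. Of 27 immediate early and heat shock genes, the transcription factors Fos at 1.15 and Egr1 at 1.43 rose and 25 did not pass. The immediate early list had a median of 0.11, and 8 rose adjusted over the list alone (camera adjusted p = 0.00883, and adjusted p = 0.434 with an estimated correlation).

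In males 3 lists passed the test in the downward direction, with no member past the threshold. Steroid and prostaglandin metabolism (23 measured; adjusted over the list alone 2 rose and 1 fell) had a median of -0.21 (camera adjusted p = 0.0169, and adjusted p = 0.191 with an estimated correlation). Saline male 4 lay apart in its mean log2 level at 9.65, against 9.33 to 9.37 in the other saline males. The unfolded protein response and amino acid stress list (21 measured) had a median of -0.16 (camera adjusted p = 0.0154, and adjusted p = 0.434 with an estimated correlation). The mitochondrially encoded genes (13 measured) had a median of -0.32 (camera adjusted p = 0.00180, and adjusted p = 0.618 with an estimated correlation). In neither of these 2 lists did a member pass adjusted over the list alone. Thus 14 of 29 tested lists passed in males with the preset correlation, and the antiviral, GTPase, chemokine and cell death lists held with an estimated correlation. The related test fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, gave 8 lists.

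The placental zone and vessel lists did not pass the test in males. The junctional zone trophoblast markers, the hormone-making layer next to the decidua, had a median of -0.16 over 25 members (camera adjusted p = 0.145). The labyrinth trophoblast markers of the exchange zone had a median of -0.01 over 23 members with a mean of 0.00298 (camera adjusted p = 0.914), the decidua and smooth muscle markers 0.12 over 20 (0.551), the yolk sac, amnion and epithelial markers -0.43 over 20 (0.117), and the endothelial and pericyte markers 0.05 over 19 (0.414). Angiogenesis and vascular tone had a median of -0.02 over 46 members, with a mean of 0.04 and a test pointing up (camera adjusted p = 0.403), and 2 members rose adjusted over the list alone. Hypoxia and glycolysis had a median of 0.09 over 32 members (camera adjusted p = 0.125), nutrient, ion and drug transport 0.01 over 37 (0.866), glucocorticoid-responsive genes 0.15 over 20 (0.0885; 1 rose adjusted over the list alone), extracellular matrix -0.04 over 35 with a test pointing up (0.979) and cell cycle 0.02 over 32 with a test pointing down (0.979). Natural killer and T cell markers had a median of -0.13 over 8 members with a mean of 0.03 (camera adjusted p = 0.861), B cell markers -0.37 over 5 (0.272) and erythroid markers 0.07 over 20 (0.540). With scaling to the total, which moved the median of all genes to 0.02, the medians of angiogenesis, labyrinth and extracellular matrix turned to 0.02, 0.03 and 0.00416. Those of transport, endothelial, erythroid and cell cycle genes were then 0.05, 0.09, 0.11 and 0.07. In mean log2 level, saline male 1 lay apart in the labyrinth list at 12.17 and the decidua list at 8.73, and PolyI:C male 3 in transport at 11.10. No member of these lists passed, and apart from the members given, none passed adjusted over the list alone.

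The next comparison asked the same question in female placentas. Cxcl10 had the largest rise there, from 19.9 ± 8.44 to 1803 ± 831 normalised reads (SD, n = 4 each), a log2 fold change of 6.399 ± 0.36 (SE, limma adjusted p = 3.62e-05). Cxcl11 went from 5.17 ± 5.88 to 407 ± 275, a log2 fold change of 6.12 ± 0.69 (limma adjusted p = 0.00933), with saline female 1 apart at 13.9. Gbp5 followed with a log2 fold change of 3.85 ± 0.30 (limma adjusted p = 0.000503), Tnfsf10 with 3.60 ± 0.57 (0.0236) and Mx1, from 174 ± 61.0 to 2362 ± 1835, with 3.43 ± 0.53 (0.0233). The other large rises were Gbp4 at 3.25, Gbp2 at 3.24, Cxcl9 at 3.10, the immunity-related GTPase Ifi47 at 3.01 and Mnda at 2.99.

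Among the falls in female placentas, Lrriq4 went from 53.9 ± 18.5 to 11.1 ± 3.66, a log2 fold change of -2.17 ± 0.37 (limma adjusted p = 0.0259). Cfap44, a component of the axoneme of cilia and flagella, went from 156 ± 69.5 to 38.6 ± 11.6, a log2 fold change of -1.94 ± 0.33 (limma adjusted p = 0.0259). Cdh17, a cadherin of intestinal epithelium, went from 232 ± 56.9 to 74.7 ± 32.9, a log2 fold change of -1.72 ± 0.35 (limma adjusted p = 0.0369). Irs3, an insulin receptor substrate, went from 1253 ± 151 to 496 ± 269.7, a log2 fold change of -1.46 ± 0.27 (limma adjusted p = 0.0330) with PolyI:C female 2 apart at 899.9, and the collagenase Mmp1 from 798 ± 239 to 301 ± 65.4, a log2 fold change of -1.38 ± 0.23 (limma adjusted p = 0.0259). The remaining large falls were Fcrl6 at -1.76, Lrtm2 at -1.64, the gastric proton pump subunit Atp4b at -1.53, Lrrc34 at -1.48 and the dynein light chain Dynlrb2 at -1.30.

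Of 14831 genes tested in female placentas, 314 passed in limma, of which 217 rose and 97 fell, and 173 of them changed at least 2-fold. An unadjusted p under 0.05 was reached by 2991 genes, against at most 2743 in the other splits of these placentas into groups of 4, and limma-voom called 240. Scaling the libraries to their totals moved the median log2 fold change of all genes to 0.18 and gave 640 genes, 581 up and 59 down, so that 90.8% rose against 69.1%. Single libraries moved the count further here. It was 3 without PolyI:C female 4, 4 without saline female 4, 5 without PolyI:C female 3, 8 without saline female 1, 22 without PolyI:C female 1 and 793 without PolyI:C female 2. Of the 72 named genes past the threshold, only Cxcl10 and Gbp5 stayed past it whichever library was left out. Limma without a trend gave 94 genes. With the junctional zone level of each placenta as a covariate, an analysis chosen after the data were seen, 0 genes passed in limma and 353 had an unadjusted p under 0.05.

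**Figure D2:**
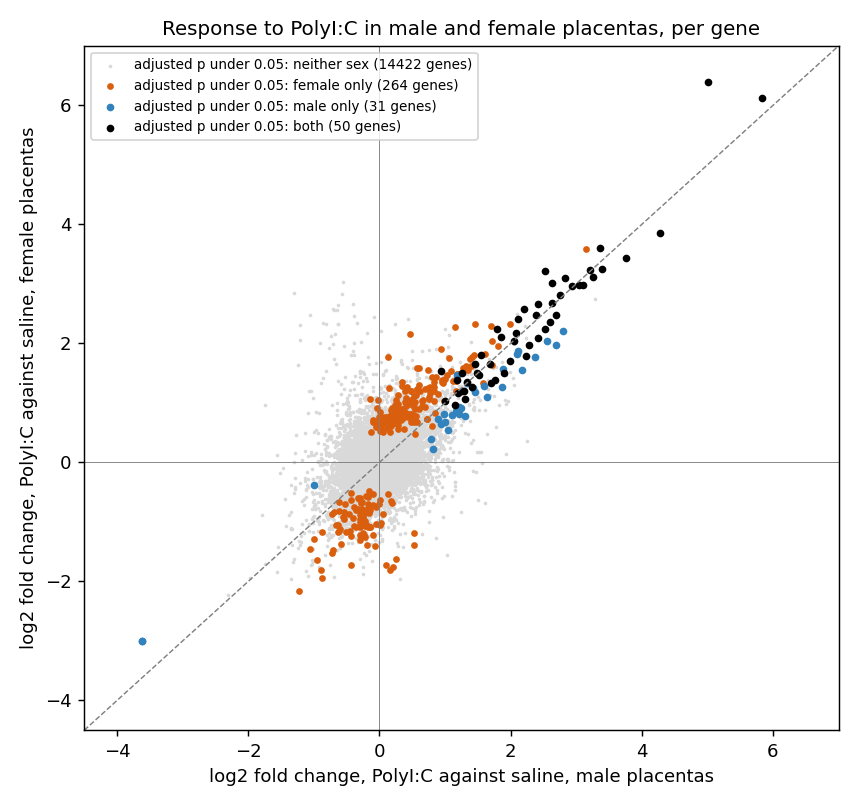
Log2 fold change of PolyI:C against saline in female placentas (y axis) against that in male placentas (x axis), with a point per gene tested in both sexes, coloured by whether the limma adjusted p was under 0.05 in males, females, both or neither, and a dashed line of equality. Both sexes called 50 genes, females alone 264, males alone 31, and 14422 genes were called in neither.

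In female placentas 20 of 42 antiviral interferon-stimulated genes rose and 22 did not pass. The antiviral list had a median of 1.19, and 32 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.76e-22, and adjusted p = 0.137 with an estimated correlation). Mx2 had a log2 fold change of 2.98 and Ifit2 of 2.97. Of 30 interferon signalling and viral RNA sensing genes 8 rose and 22 did not pass, among them Zbp1 at 3.22 and Ddx58 at 2.18. The interferon signalling list had a median of 0.53, and 15 rose adjusted over the list alone (camera adjusted p = 3.08e-09, and adjusted p = 0.137 with an estimated correlation). Of 8 guanylate-binding proteins and immunity-related GTPases 6 rose and 2 did not pass. The GTPase list had a median of 2.91, and 7 rose adjusted over the list alone (camera adjusted p = 6.97e-10, and adjusted p = 0.121 with an estimated correlation). Antigen processing and MHC class I genes rose in 6 of 17 members and 11 did not pass. The antigen processing list had a median of 0.74, and 11 rose adjusted over the list alone (camera adjusted p = 2.82e-09, and adjusted p = 0.137 with an estimated correlation). Psmb9 had a log2 fold change of 2.30, Nlrc5, a transcriptional activator of MHC class I, of 2.04, Tap1 of 1.96 and the class I gene RT1-N3 of 1.43. None of 10 MHC class II genes passed in females, also adjusted over the list alone, with a median of -0.15 that turned to 0.03 with scaling to the total (camera adjusted p = 0.772).

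Chemokines rose in females in 4 of 19 members, Cxcl9, Cxcl10, Cxcl11 and Cx3cl1, the ligand of a receptor on monocytes, at 1.76, and 15 did not pass. Adjusted over the list alone 11 chemokines rose and 2 fell, and the median was 1.17 (camera adjusted p = 2.38e-08, and adjusted p = 0.109 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in 11 of 33 members and 22 did not pass. The inflammatory list had a median of 0.83, and 22 rose adjusted over the list alone (camera adjusted p = 5.30e-15, and adjusted p = 0.109 with an estimated correlation). Vcam1 went from 108 ± 39.7 to 508 ± 141, the NF-kB inhibitor Tnfaip3 had a log2 fold change of 1.91 and the macrophage growth factor Csf1 of 1.59. Complement and coagulation genes rose in 3 of 33 members, C1r at 1.75, C1s at 1.51 and Cfb at 1.24 (with PolyI:C female 1 apart at 1524), and 30 did not pass. The complement list had a median of 0.50, and 8 rose adjusted over the list alone (camera adjusted p = 3.39e-07, and adjusted p = 0.109 with an estimated correlation). Over the 16 placentas, saline female 1 had the lowest mean log2 level both of this list, at 7.62, and of the yolk sac, amnion and epithelial markers, at 6.73, and PolyI:C female 1 the highest of both, at 9.26 and 11.7. Saline female 1 was also the lowest of the 16 in the erythroid markers, at 8.73, and in nutrient, ion and drug transport, at 10.6. Cell death genes rose in 2 of 25 members, Tnfsf10 and the tumour necrosis factor receptor Tnfrsf1a at 0.76, and 23 did not pass. The cell death list had a median of 0.44, and 10 rose adjusted over the list alone (camera adjusted p = 3.32e-06, and adjusted p = 0.15 with an estimated correlation).

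Of the leukocyte lists, those of neutrophils and of macrophages passed the preset test in females, in the upward direction. Of 12 neutrophil markers Mmp8 at 2.04 and S100a8, from 64.1 ± 15.8 to 234 ± 101 with PolyI:C female 1 apart at 386, rose and 10 did not pass. The neutrophil list had a median of 1.14, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.70e-05, and adjusted p = 0.114 with an estimated correlation). Of 20 macrophage and monocyte markers the pore-forming Mpeg1 rose at 1.48 and 19 did not pass. The macrophage list had a median of 0.54, and 2 rose adjusted over the list alone (camera adjusted p = 0.000641, and adjusted p = 0.256 with an estimated correlation). No natural killer and T cell marker of 8 passed, with a median of 0.09 (camera adjusted p = 0.440), and the 4 measured B cell markers, too few for the test, had a median of -0.38. Erythroid markers (20 measured, none past the threshold, 1 rose adjusted over the list alone) had a median of 0.23 (camera adjusted p = 0.0373, and adjusted p = 0.567 with an estimated correlation).

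The junctional zone trophoblast markers shifted down in female placentas. Of 25 members 3 fell and 22 did not pass. The junctional zone list had a median of -0.92, and 13 fell adjusted over the list alone (camera adjusted p = 3.26e-09, and adjusted p = 0.109 with an estimated correlation). The 3 were the pregnancy-specific glycoproteins Psg29, from 161965 ± 41200 to 75749 ± 16597, and Psg16 at a log2 fold change of -1.06, and the related Ceacam3 at -1.08, in families whose members share sequence. Saline female 1 lay above the other saline females in Psg29, at 223120, and in Psg16, at 79412. In the mean log2 level of the whole list saline female 2 lay below the other saline females, at 13.64 against 14.21 to 14.29, with PolyI:C females up to 13.5. Labyrinth trophoblast markers did not pass in any of 23 members. The labyrinth list had a median of 0.36, and 6 rose adjusted over the list alone (camera adjusted p = 0.000508, and adjusted p = 0.189 with an estimated correlation). Of 20 decidua and smooth muscle markers 6 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone, and the median was 0.32 (camera adjusted p = 0.00120, and adjusted p = 0.137 with an estimated correlation). The smooth muscle genes Actg2 at 1.29 and Myh11 at 0.88, the matrix proteoglycan Lum at 1.21 and the growth factor Bmp2 at 1.07 were among the rises, and the fall was the decidual prolactin Prl8a2 at -0.99. Yolk sac, amnion and epithelial markers did not pass in any of 20 members, also adjusted over the list alone, with a median of 1.80 (camera adjusted p = 8.96e-05, and adjusted p = 0.407 with an estimated correlation).

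Angiogenesis and vascular tone genes rose in females in 8 of 46 members, 1 fell and 37 did not pass, while 18 rose and 3 fell adjusted over the list alone, and the median was 0.51 (camera adjusted p = 1.60e-08, and adjusted p = 0.109 with an estimated correlation). The lipase inhibitor Angptl4 had a log2 fold change of 1.41, the apelin receptor Aplnr of 1.05, the angiotensin receptor Agtr1a of 0.80 and the sphingosine phosphate receptor S1pr1 of 0.73. The fall was the natriuretic peptide Nppb, at -1.17. In the same placentas the mean log2 level of the junctional zone list was 14.1 ± 0.307 in saline and 13.3 ± 0.143 in PolyI:C females (SD, n = 4 each). Of 19 endothelial and pericyte markers the potassium channel Kcnj8 rose at 1.59 and 18 did not pass. The endothelial list had a median of 0.57, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.60e-08, and adjusted p = 0.109 with an estimated correlation). Extracellular matrix genes rose in 2 of 35 members, Col6a3 at 1.04 and the crosslinking enzyme Lox at 0.96, and 33 did not pass. The matrix list had a median of 0.33, and 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.20e-05, and adjusted p = 0.229 with an estimated correlation).

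Glucocorticoid-responsive genes rose in females in 3 of 20 members, the pyruvate dehydrogenase kinase Pdk4 at 1.24, Angptl4 and the iron-binding Lcn2 at 1.36, and 17 did not pass. The glucocorticoid list had a median of 0.31, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000466, and adjusted p = 0.109 with an estimated correlation). Of 27 immediate early and heat shock genes Fos rose at 0.96 and 26 did not pass. The immediate early list had a median of 0.27, and 3 rose adjusted over the list alone (camera adjusted p = 0.0150, and adjusted p = 0.381 with an estimated correlation). Of 23 steroid and prostaglandin genes the steroid reductase Srd5a1 rose, from 690.4 ± 177 to 1752 ± 319, and 22 did not pass, 1 rose and 2 fell adjusted over the list alone, and the median of -0.08 turned to 0.11 with scaling to the total (camera adjusted p = 0.494). Nutrient, ion and drug transport had a median of 0.22 over 37 members (camera adjusted p = 0.00453, and adjusted p = 0.272 with an estimated correlation), and the unfolded protein response and amino acid stress list -0.19 over 21, which turned to -0.00309 with scaling to the total (camera adjusted p = 0.00668, and adjusted p = 0.198 with an estimated correlation). No member of these 2 lists passed, also adjusted over the list alone. Hypoxia and glycolysis had a median of 0.07 over 32 members (camera adjusted p = 0.161; 1 rose adjusted over the list alone), cell cycle 0.15 over 32 (0.195) and the mitochondrially encoded genes -0.12 over 13 (0.440), which turned to 0.07 with scaling to the total. With scaling to the total the medians of the transport, labyrinth, decidua, erythroid, immediate early, glucocorticoid and matrix lists were 0.41, 0.55, 0.51, 0.42, 0.46, 0.50 and 0.52. Those of hypoxia, cell cycle and natural killer and T cell genes were 0.26, 0.34 and 0.28. In all, 22 of 28 tested lists passed in females with the preset correlation, 20 up and 2 down, none held with an estimated correlation, and fry gave 16.

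The male and female responses were then compared gene by gene. Among 14767 genes tested in both sexes, 50 rose in both, where independent lists of these sizes share 1.15, and none fell in both (0.0197). Of the 314 genes past the threshold in females, 289 had the same sign in males, and of the 81 in males, 81 had the same sign in females, with a median absolute log2 fold change of 1.88 in males and 1.66 in females. Over 14937 genes the log2 fold changes of the sexes correlated at 0.494 with a covariance of 0.0915, across genes, which are not independent replicates. Because male and female placentas shared dams, the same values were computed for 18 splits of the dams with no treatment effect, which gave a mean correlation of 0.0840 (-0.218 to 0.519) and a mean covariance of 0.00630 with a highest value of 0.0447. The observed correlation thus lay within the range of these splits, while the observed covariance lay above their highest. When males and females were taken from different dams, over 36 partings, the mean correlation was 0.314 (-0.0904 to 0.612) and the mean covariance 0.0852. Each fold change then rested on fewer dams. This mean covariance equals, by construction, the observed one less the mean over the splits, so it is no separate check.

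With the dam as the unit, the mean of its male and female placenta was compared between 4 saline and 4 PolyI:C dams. Cxcl11 had a log2 fold change of 5.98 ± 0.56 (SE, limma adjusted p = 0.000833), Cxcl10 of 5.67 ± 0.31 (1.79e-05), Gbp5 of 4.05 ± 0.24 (2.21e-05) and Mx1 of 3.59 ± 0.38 (0.00159). Vcam1 at 2.02 ± 0.18, Mmp8 at 2.04 ± 0.20 and S100a8 at 1.66 ± 0.18 also rose, with limma adjusted p values of 0.000588, 0.00114 and 0.00194. The falls included Lrriq4 at -1.85 ± 0.30, Cfap44 at -1.42 ± 0.24 and Irs3 at -1.27 ± 0.21, each with a limma adjusted p of 0.0134. Lrriq4 missed the threshold without saline dam 3 (adjusted p = 0.0520), and Irs3 and Cfap44 without PolyI:C dam 4 (0.0562 each).

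Of 14856 genes tested per dam, 307 passed in limma, of which 210 rose and 97 fell, and 146 of them changed at least 2-fold. An unadjusted p under 0.05 was reached by 2921 genes, and limma-voom called 239. The former number was reached by 3 of the 35 splits of the dams, the real one included (highest other 3205). Scaling to the total moved the median of all genes to 0.10 and gave 332 genes, 280 up and 52 down, so that 84.3% rose against 68.4%. The count was 85 without PolyI:C dam 4, 107 without PolyI:C dam 1, 114 without PolyI:C dam 3, 118 without saline dam 3, 126 without saline dam 4, 173 without saline dam 1 and 804 without PolyI:C dam 2. Taking the 16 placentas as separate samples gave 795 genes, limma-voom with the dam as a random effect 652, and limma without a trend on the dam means 203.

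Per dam, 23 of 42 antiviral interferon-stimulated genes rose and 19 did not pass, 36 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.79e-31, and adjusted p = 0.184 with an estimated correlation). Of 8 guanylate-binding proteins and immunity-related GTPases 7 rose and 1 did not pass, also adjusted over the list alone (camera adjusted p = 7.96e-14, and adjusted p = 0.184 with an estimated correlation), with Gbp2 at 3.24. Interferon signalling genes rose in 12 of 30 members and 18 did not pass, 17 rose adjusted over the list alone (camera adjusted p = 3.65e-11, and adjusted p = 0.184 with an estimated correlation). Antigen processing and MHC class I genes rose in 7 of 17 members and 10 did not pass, 11 rose adjusted over the list alone (camera adjusted p = 4.48e-10, and adjusted p = 0.184 with an estimated correlation). Chemokines rose in 6 of 20 members and 14 did not pass, 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.30e-09, and adjusted p = 0.184 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in 8 of 33 members and 25 did not pass, 23 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.74e-13, and adjusted p = 0.184 with an estimated correlation). Cell death genes rose in 6 of 25 members and 19 did not pass, 12 rose adjusted over the list alone (camera adjusted p = 2.50e-07, and adjusted p = 0.184 with an estimated correlation), with Mlkl at 1.36, Casp4 at 1.02 and the death receptor Fas at 0.91.

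Among leukocyte and stress genes per dam, 4 of 11 neutrophil markers rose, Mmp8, S100a8, S100a9 at 1.32 and Retnlg at 1.40, the gelatinase Mmp9 fell at -0.83 and 6 did not pass, 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.76e-06, and adjusted p = 0.184 with an estimated correlation). Fcgr3a at 2.27 and Mpeg1 at 1.34 rose among 21 macrophage and monocyte markers and 19 did not pass, also adjusted over the list alone (camera adjusted p = 3.02e-05, and adjusted p = 0.186 with an estimated correlation). Fos at 1.07 and the stress-induced Atf3 at 0.87 rose among 27 immediate early and heat shock genes and 25 did not pass, 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.442 with an estimated correlation). Pdk4 at 1.03 and Angptl4 at 1.21 rose among 20 glucocorticoid-responsive genes and 18 did not pass, 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00520, and adjusted p = 0.233 with an estimated correlation). C1r at 1.57 and C1s at 1.51 rose among 33 complement and coagulation genes and 31 did not pass, 8 rose adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.184 with an estimated correlation).

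None of 25 junctional zone markers passed per dam. The junctional zone list had a median of -0.54, and 5 fell adjusted over the list alone (camera adjusted p = 7.42e-06, and adjusted p = 0.186 with an estimated correlation). Kcnj8 rose at 1.06 and the pericyte receptor Pdgfrb fell at -0.56 among 19 endothelial and pericyte markers and 17 did not pass, 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.33e-05, and adjusted p = 0.186 with an estimated correlation). Angptl4, the vasoconstrictor Edn1 at 1.46 and Agtr1a at 0.53 rose among 46 angiogenesis and vascular tone genes and 43 did not pass, 11 rose and 3 fell adjusted over the list alone (camera adjusted p = 5.15e-05, and adjusted p = 0.217 with an estimated correlation). The hepatocyte growth factor receptor Met rose at 0.84, the 1 labyrinth marker of 23 to pass, also adjusted over the list alone, and Srd5a1 rose at 1.14, the 1 steroid gene of 23 (2 rose and 3 fell adjusted over the list alone). The labyrinth, decidua and transport lists each had a camera adjusted p of 0.0386, with an adjusted p = 0.380, 0.380 and 0.442 with an estimated correlation. The yolk sac list shifted up (camera adjusted p = 0.01, and adjusted p = 0.538 with an estimated correlation), and the unfolded protein response list (0.00202, and adjusted p = 0.247 with an estimated correlation) and the mitochondrially encoded genes (0.0329, and adjusted p = 0.544 with an estimated correlation) shifted down, at medians of -0.19 and -0.22 that turned to -0.07 and -0.11 with scaling to the total. The list of extracellular matrix genes (35 measured) held 1 fall, Mmp9, with 2 rises and 1 fall adjusted over the list alone and a median of 0.19 (camera adjusted p = 0.00642, and adjusted p = 0.485 with an estimated correlation). With scaling to the total the medians of the transport, labyrinth, immediate early, glucocorticoid and matrix lists went from 0.10, 0.11, 0.14, 0.17 and 0.19 to 0.21, 0.23, 0.25, 0.29 and 0.31. Of 29 lists tested per dam 22 passed with the preset correlation, 19 up and 3 down, none with an estimated correlation (lowest adjusted p 0.184), and fry gave 13.

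**Figure D3:**
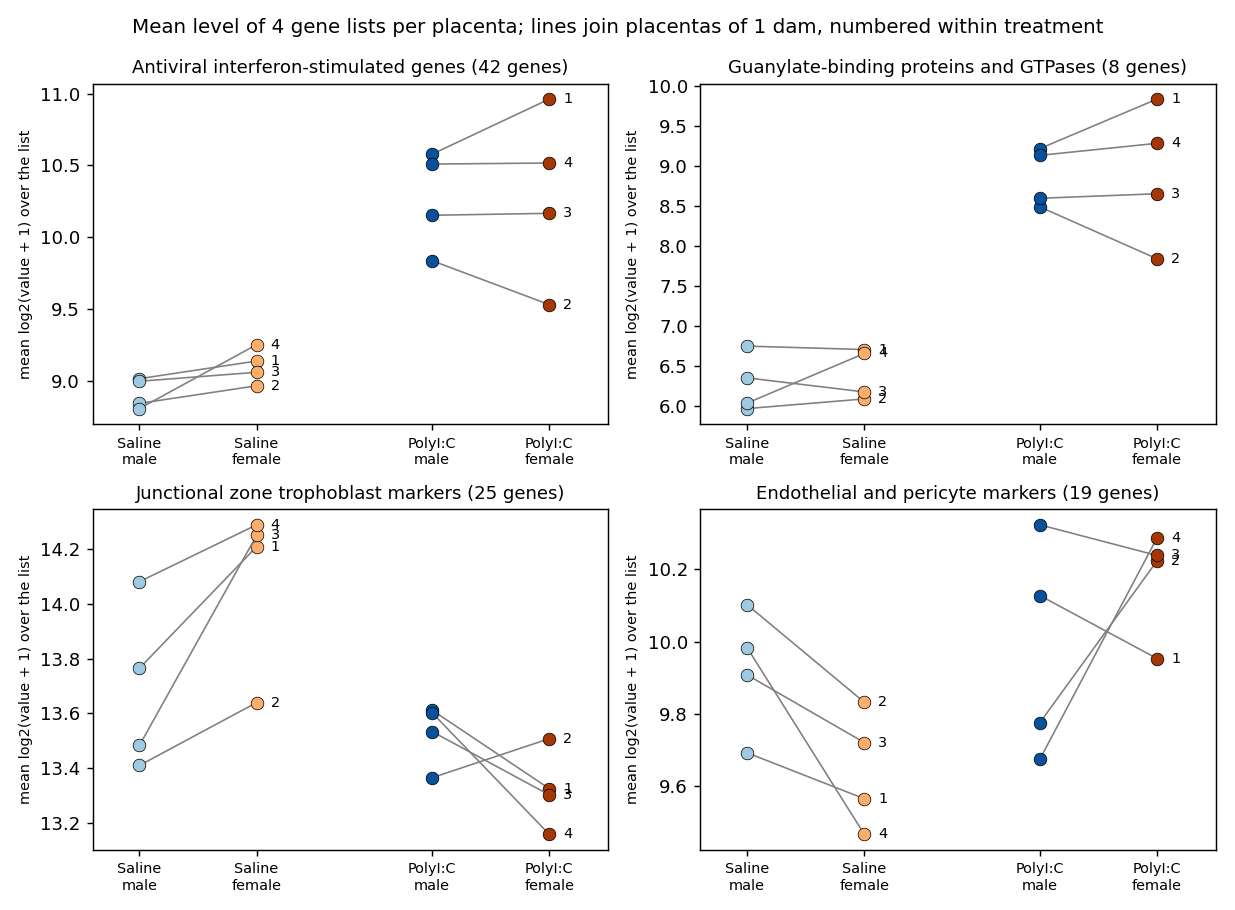
Mean log2 normalised read count over the 42 antiviral genes, 8 GTPases, 25 junctional zone markers and 19 endothelial markers in each placenta, by treatment and sex, with a line joining the male and female placenta of a dam. In the antiviral list both placentas of PolyI:C dam 2, at 9.84 and 9.53, lie below those of the other PolyI:C dams and above the highest saline placenta at 9.25.

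The difference between the sexes in their response to PolyI:C was tested as an interaction. Mmp1 had the smallest p, with means of 509.6 ± 187 in saline and 724 ± 226 in PolyI:C males against 798 ± 239 and 301 ± 65.4 in females, a difference of the male minus the female log2 fold change of 1.90 ± 0.40 (SE). Slc45a3, a sugar transporter, followed at -1.29 ± 0.27, and Id3, an inhibitor of helix-loop-helix transcription factors, at -0.96 ± 0.22. Spry1, a feedback inhibitor of growth factor signalling, was at -0.77 ± 0.18, the G protein subunit Gna14 at 1.13 ± 0.26, the interleukin receptor chain Il3ra at -0.81 ± 0.19, Crmp1 at -1.45 ± 0.35, Sash3 at -1.75 ± 0.43, the intermediate filament Nes at -0.94 ± 0.23 and Tmc5 at 1.71 ± 0.43. None of these 10 genes passed, each with a limma adjusted p of 0.816. Of 14937 genes tested 0 passed in limma, 810 had an unadjusted p under 0.05, a number that 7 of the 35 assignments of the dams reached, the real one included, and limma-voom called 0. The male-only and female-only calls given above are therefore not shown to differ between the sexes. Scaling to the total shifted the median difference of all genes to -0.16.

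At the level of lists, 10 of 29 differed between the sexes by the preset test, while no member of any list passed, also adjusted over the list alone. The male minus the female log2 change was positive in 1 of these lists, the junctional zone markers, whose median fell less in males than in females. Their median difference was 0.76, with 22 of 25 members above 0 (camera adjusted p = 2.83e-06, and adjusted p = 0.344 with an estimated correlation). This signed difference, which does not measure the strength of a response, was negative in the others. It was -0.48 for the endothelial and pericyte markers (camera adjusted p = 2.83e-06, and adjusted p = 0.344 with an estimated correlation), -2.33 for the yolk sac, amnion and epithelial markers (3.36e-06, and adjusted p = 0.596 with an estimated correlation) and -0.38 for angiogenesis and vascular tone (7.90e-06, and adjusted p = 0.344 with an estimated correlation). The extracellular matrix had a median of -0.34 (camera adjusted p = 0.000471, and adjusted p = 0.716 with an estimated correlation), the labyrinth markers -0.34 (0.000908, and adjusted p = 0.573 with an estimated correlation) and the inflammatory list -0.26 (0.00201, and adjusted p = 0.596 with an estimated correlation). Transport at -0.21 (camera adjusted p = 0.0197), complement at -0.21 (0.0252) and the mitochondrially encoded genes at -0.32 (0.0252) had an adjusted p = 0.596, 0.596 and 0.825 with an estimated correlation. With scaling to the total the inflammatory, transport and complement medians were -0.41, -0.36 and -0.35. With the dam as a block, 12 lists passed, which added the antiviral genes (0.00965) and antigen processing (0.0126). No list passed fry. The interaction shares its placentas with the comparisons within females and of the sexes within a treatment, so these list results are not separate findings. In the junctional zone list the mean log2 level was 13.7 in saline males and 14.1 in saline females. In PolyI:C males and females it was 13.5 and 13.3, so the gap between the sexes was wider in saline.

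Male and female placentas were last compared within each treatment. In saline placentas Ddx3, an RNA helicase gene, was higher in males by a log2 difference of 7.47 ± 0.59 (SE, limma adjusted p = 0.00109), and in PolyI:C placentas by 7.86 ± 0.49 (8.29e-05), with 557 to 2545 normalised reads in male and 2.10 to 20.9 in female libraries. Ddx3 is also listed as an older symbol of the Y-linked Ddx3y. A separate gene under the name Ddx3y was also measured and did not pass in either treatment. The Ddx3 values in female libraries, at most 20.9 against 557 or more in males, argue against a locus that both sexes express. Which locus the annotation gives this name was not settled here. The unnamed gene AC239701.1, picked out after its values were seen, differed by 5.66 ± 0.53 in saline (limma adjusted p = 0.00292) and 5.70 ± 0.25 in PolyI:C placentas (4.30e-06). In saline the next genes were the dynein chain Dnai2 at -2.09, the signal transducer Smad3 at -0.73 and the phosphatase Cdc14a at -0.80 (limma adjusted p = 0.539 each), and in PolyI:C placentas Il3ra at -0.98 (0.0716), Slc45a3 at -0.86 (0.430) and Mmp1 at 1.24 (0.768).

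Of 14791 genes in saline and 14817 in PolyI:C placentas, Ddx3 and AC239701.1 were the 2 that passed in limma in each treatment, both higher in males, and 679 and 849 genes had an unadjusted p under 0.05, numbers that 16 and 8 of the 35 splits of the placentas reached, the real one included. Limma-voom called 1 gene in saline and 2 in PolyI:C placentas. Ddx3 missed the threshold of limma-voom in saline (adjusted p = 0.104), while the log2 difference stayed between 6.19 and 7.99 over all settings run. In limma with a trend, without any 1 of the 4 male libraries of a treatment Ddx3 alone passed, because AC239701.1 then reached a value of 10 in fewer than 4 libraries and was not tested. Of the 5 sex-linked genes measured, 1 was higher in males in saline and 1 in PolyI:C placentas, 2 in the latter adjusted over the list alone. That list had a median of -0.07 in saline, 0.02 with scaling to the total, with a mean of 1.44 and a test pointing up (camera adjusted p = 0.223), and 0.19 in PolyI:C placentas (camera adjusted p = 0.0117, and adjusted p = 0.697 with an estimated correlation).

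In saline placentas 8 of 30 lists differed between the sexes by the preset test, with no member past the threshold, also adjusted over the list alone. The junctional zone markers were lower in males at a median of -0.55 (camera adjusted p = 4.49e-06, and adjusted p = 0.556 with an estimated correlation), as were the antiviral genes at -0.22, which turned to -0.13 with scaling to the total (3.55e-05, and adjusted p = 0.431 with an estimated correlation). The endothelial and pericyte markers were higher in males at 0.32 (camera adjusted p = 4.49e-06, and adjusted p = 0.431 with an estimated correlation), angiogenesis and vascular tone at 0.22 (5.10e-05, and adjusted p = 0.556 with an estimated correlation), and the mitochondrially encoded genes at 0.28 (0.000170, and adjusted p = 0.708 with an estimated correlation). The yolk sac markers were at 1.18 (camera adjusted p = 0.000527), the labyrinth markers at 0.18 (0.00690) and the inflammatory list at 0.16 (0.0248), with an adjusted p = 0.708, 0.584 and 0.481 with an estimated correlation. Scaling to the total moved the median of all genes to 0.09 and those of the labyrinth and inflammatory lists to 0.27 and 0.25. With the dam as a block 9 lists passed, the added one being the erythroid markers (0.0397).

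In PolyI:C placentas 11 of 29 lists differed by the preset test, each with an adjusted p = 0.697 with an estimated correlation. The junctional zone markers were higher in males at a median of 0.22 (camera adjusted p = 0.00979; 1 member higher adjusted over the list alone). The extracellular matrix was lower in males at -0.32 (camera adjusted p = 1.88e-05), the yolk sac markers at -1.09 (0.000252), antigen processing at -0.30 (0.00411) and angiogenesis and vascular tone at -0.15 (0.0146). The decidua markers were at -0.22 (camera adjusted p = 0.0269), the endothelial markers at -0.14 (0.0285), complement at -0.20 (0.0288), the glucocorticoid-responsive genes at -0.21 (0.0288) and the labyrinth markers at -0.10 (0.0396), which turned to -0.15 with scaling to the total, where the median of all genes was -0.07. No member of these 10 lists passed. With the dam as a block 12 lists passed, the labyrinth markers were lost (0.0644), and the inflammatory list (0.0109) and the cell death list (0.0331) were added. No list passed fry in either treatment.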

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

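Of the tests in this part, the same response in both sexes and tissue sampling were chosen before their result was seen, and the fits that leave out 1 library, limma-voom and the list tests were planned before the data were examined. The counts over other splits of the placentas and the other tests were chosen only afterwards, as was the use of the planned fits to weigh single libraries.

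For PolyI:C against saline, the counts of genes at an adjusted p under 0.05 were set against all 35 splits of the samples into groups of 4. In each comparison the splits argue against chance but cannot exclude it, since 1 of 35 is the smallest share they can give. The comparisons also share dams, so their results are not independent. The real split gave 81 genes in males where the highest of the other splits gave 24, 314 in females against 30, and 307 per dam against 2, so that 1 of the 35 splits, the real one, gave as many. At an unadjusted p under 0.05 this held in females alone, where 1 of 35 reached the real 2991 genes (highest other 2743): in males 6 of 35 reached 1318 (highest other 2669) and per dam 3 of 35 reached 2921 (highest other 3205), so chance cannot be excluded for those 2 counts. For the sex difference of the response 0 genes passed in limma and in limma-voom, a count that all 35 assignments reach by construction (highest other 0) and that decides nothing, and the 810 genes at an unadjusted p under 0.05 were reached by 7 of 35 (highest other 2421), so chance cannot be excluded for them.

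In males against females, chance cannot be excluded from the number of genes alone. In saline 2 of 35 splits reached 2 genes, and the highest other, which parted 2 of the 4 dams' pairs, gave 17, several times the real count. The cause of that count was not tested. In PolyI:C placentas 2 of 35 splits did and the highest other gave 6. Among the 8 splits that part the placentas of every dam, as the real split does, which are too few for a share under 0.05, the real one gave 2 genes and the highest other 0. The 2 genes themselves argue against chance: Ddx3 and AC239701.1 passed in limma in both treatments, which share no dam (Ddx3 not in limma-voom in saline, adjusted p = 0.104), and Ddx3 was at 557 or more in every male library and at 20.9 or less in every female library.

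More genes passed in female than in male placentas, 314 against 81. Whether single libraries set the female count stays open: over the 8 fits that leave out 1 library the median count was 15 in females and 48 in males, with 5 different libraries each taking the female count to 22 or fewer, but at an unadjusted p under 0.05 it was 2504.5 (1975 to 3387) in females and 1060 (828 to 2363) in males. A response shared by both sexes also met what it predicts, since the number of genes at an unadjusted interaction p under 0.05, 810, was reached by 7 of 35 assignments of the dams (highest 2421). With the junctional zone level as a covariate the counts were 0 in females and 62 in males, which is what tissue sampling would give, but that level separates the female groups (highest PolyI:C placenta 13.5, lowest saline placenta 13.6), so sampling and treatment cannot be told apart there. A difference of the sexes in their response stays open too.

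Junctional zone genes were lower in PolyI:C than in saline female placentas, by 0.774 in the list's mean log2 level (14.1 ± 0.307 to 13.3 ± 0.143; SD, n = 4 each), against 13.7 ± 0.306 and 13.5 ± 0.114 in males. Library scaling is excluded as the cause, since the list's median change was still -0.73 under the scaling that brought it nearest to 0. A smaller share of junctional zone as the sole cause would move all other zones alike only if their lists hold no genes expressed in the junctional zone, which was not tested. The endothelial list moved apart from the labyrinth list (difference of shifts, labyrinth minus endothelial, -0.24) and from the decidual list (0.19). Each had an exact permutation p of 0.0286, the smallest that 4 against 4 can give, unadjusted over the pairs, while the third of the 3 pairs had an exact p of 0.600. A smaller share as the sole cause therefore stays open. Zones sampled differently cannot be told apart from an effect of treatment. The 8 saline placentas of both sexes spanned 0.88 (13.4 to 14.3), but the lowest was a male. Saline females alone lay at 13.64 to 14.29, a narrower range than the fall, so the span does not decide. A lower expression in the junctional zone itself may add to the fall and was not tested.

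Both placentas of PolyI:C dam 2 showed a weaker interferon response, with a mean log2 level of the antiviral list of 9.84 in the male (other PolyI:C males 10.2 to 10.6) and 9.53 in the female (others 10.2 to 10.96). Saline placentas under a wrong label are excluded, since the lower of them lay 0.28 above the highest saline placenta at 9.25, against an SD of 0.146 among saline placentas. Lower depth is excluded as well: the shallower of these libraries held 27.7 M estimated reads and another PolyI:C library 27.3 M. A fault of a single library stays open, since 2 of 2 placentas of the dam were the lowest of their sex in the antiviral and in the GTPase list but chance gives such a match for 1 of the 4 dams with a probability of 0.25. A lower dose or a slower response in this dam may explain it and was not tested.

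The lists whose responses differed between the sexes by camera's preset test had adjusted p values of 2.83e-06 for the junctional zone and for the endothelial markers, 3.36e-06 for the yolk sac markers, 7.90e-06 for angiogenesis, 0.000471 for extracellular matrix, 0.000908 for labyrinth markers, 0.00201 for inflammatory genes, 0.0197 for transport, and 0.0252 for complement and for the mitochondrially encoded genes, and none held with an estimated correlation in limma.

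Single placentas lay far from the other 3 of their group in 31 of 536 groups of 4 tested, 5.78%, where chance gives about 5%. The identical unnamed genes were counted separately there. The flags were not spread evenly, and saline male 4 had the most. Saline male 4 was high in Tap1 at 404.4 normalised reads (others 291 to 300.1), Cfap44 at 124 (82.6 to 84.4), Fcrl6 at 390.0 (86.9 to 114), Nppb at 2178 (535 to 756) and the identical ENSRNOG00000062337 and ENSRNOG00000065674 at 28759 (4160 to 5953), and low in Casp4 at 64.0 (99.6 to 106) and Agtr1a at 401 (497 to 516). Among other saline males, Lrtm2 was 54.8 in saline male 2 (29.6 to 31.8), Nlrc5 128 in saline male 3 (75.2 to 80.2) and Lcn2 113 in saline male 1 (39.4 to 46.8). Saline female 1 was high in Cxcl11 at 13.9 (1.07 to 3.15), Psg16 at 79412 (64048 to 66414) and Psg29 at 223120 (133436 to 147412), saline female 2 in Myh11 at 753 (555 to 569), and saline female 3 in Psmb9 at 108 (74.6 to 77.6) and Atp4b at 132 (87.5 to 93.8). Of the PolyI:C males, male 1 was high in Mmp9 at 722 (304 to 332), male 2 in Lrrc34 at 100.0 (24.7 to 37.2) and low in Nppb at 498 (665 to 683), and male 3 was high in S1pr1 at 1098 (818 to 864). PolyI:C female 1 was high in S100a8 at 386 (171 to 190.5) and Cfb at 1524 (785 to 899.7), and PolyI:C female 2 in Irs3 at 899.9 (342 to 371).

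In mean log2 level of a list, saline male 4 was apart in steroid metabolism at 9.65 (others 9.33 to 9.37) and macrophage markers at 6.22 (6.74 to 6.81), saline male 1 in labyrinth markers at 12.17 (12.42 to 12.43) and decidual markers at 8.73 (9.32 to 9.42), saline female 2 in junctional zone markers at 13.64 (14.21 to 14.29), PolyI:C male 3 in transport at 11.10 (10.93 to 10.95) and PolyI:C male 1 in cell death at 7.58 (7.33 to 7.37).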

How the results depend on the processing

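The settings chosen after the data were seen were both other scalings, the pseudocounts, limma without a trend and the junctional zone covariate. The rest were planned. The planned edgeR and DESeq2 tests were not run because the values are not counts. Median-of-ratios scaling, also planned, was not run either, although other scalings were run on the estimated reads. In females, limma calls went from 314 genes to 640 with scaling to the total, 94 without a trend, 173 with a log2 fold change of at least 1, and 0 with the covariate (353 at an unadjusted p under 0.05), under which Dynlrb2 also turned to a log2 change of 0.00149; the fold threshold removes genes by construction, and for the others the cause was not tested. A replicate block took the female count to 50, of which 48 were shared, although the numbers do not pair placentas across treatments, whose dams differ. In males the block gave 55 and per dam 272. Across treatments the mean correlation was -0.0934 over 8 same-numbered pairs and 0.0326 over 24 others. Deviations sum to 0 within a group, so the second value largely follows from the first and is no control. Per dam, 307 genes became 795 with the 16 placentas as separate samples, 652 in limma-voom with the dam as a random effect (dam correlation 0.0371), 203 without a trend and 146 with the fold threshold. The first 2 use 16 libraries in place of 8 dam means and the random effect also came with voom, so that several choices changed at once, and the cause was not tested there or without a trend. In saline placentas limma-voom found 1 sex difference in place of 2. The lost gene was Ddx3, whose adjusted p ranged from 1.57e-05 to 0.104 over all settings, the latter in limma-voom, with log2 differences of 6.19 to 7.99, and the cause was not tested.

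Leaving out 1 library moved the male count over 34 to 130, the female count over 3 to 793, the sex difference over 0 to 0, males against females over 1 to 3 in saline and 1 to 2 in PolyI:C placentas, and leaving out a dam moved the count per dam over 85 to 804. Without saline dams 1, 3 and 4 it was 173, 118 and 126, and without PolyI:C dams 1 and 3 it was 107 and 114; fewer samples lower the power, and the rise to 793, 804 and 130 came without PolyI:C female 2, dam 2 and male 2, which had the lowest antiviral and GTPase list levels among the PolyI:C placentas of their sex. With an estimated correlation the lists past the threshold went from 14 to 4 in males, from 22 to 0 in females and per dam, from 10 to 0 for the sex difference, and from 8 and 11 to 0 for males against females; fry gave 8, 16, 13, 0, 0 and 0. The dam as a block changed no call of a gene in the sex difference or in males against females, and moved the list counts there from 10 to 12, 8 to 9 and 11 to 12. Over all genes, libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 38.3 to 201, a figure that does not speak for genes of few reads such as Cxcl11 in saline placentas.

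Of the named genes past the threshold, the 40 in males kept it in 391 of 437 values under other settings and in 214 of 304 with a library left out, the 72 in females in 602 of 790 and in 217 of 568, and the 33 per dam in 348 of 361 and in 207 of 264. Apart from Dynlrb2, no named gene past the threshold changed sign in these comparisons. Of the 3 genes named as not past it in males (Psmb9, Tap1 and Dio3) and the 2 in females (ENSRNOG00000062337 and ENSRNOG00000065674, which hold identical values), the threshold was passed in 2 values per sex under other settings and in 2 per sex with a library left out, none of them of Dio3.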

Other observations

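Of the tests in this part, the 1 on cilia genes was chosen only after its result was seen, and the genes named here were chosen after their values were seen.

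Of the 50 genes that rose in both sexes, 17 belonged to none of the 30 lists, and 10 of those have a symbol: Mnda, RT1-CE11 and the 8 that follow. Hsh2d, an adaptor protein of lymphocytes, had a log2 fold change of 2.38 in males (limma adjusted p = 7.03e-05) and 2.48 in females (0.0156). Uba7, the enzyme that activates the ubiquitin-like modifier ISG15, rose by 2.42 and 2.65 on the log2 scale, the large ubiquitin ligase Rnf213 by 2.64 and 2.67, and Samhd1, which hydrolyses deoxynucleotides and restricts viruses, by 1.85 and 2.12. Znfx1, a helicase-like sensor of viral RNA, was at 1.52 and 1.47, the signal transducer Stat4 at 1.19 and 1.16, and Cnp, a phosphodiesterase best known from myelin, at 1.26 and 1.21. Vcan, a large matrix proteoglycan, went from 186 ± 61.0 to 509 ± 148 normalised reads in males and from 152.5 ± 37.6 to 488 ± 149.6 in females (SD, n = 4 each).

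Dio3, the deiodinase that inactivates thyroid hormone and is abundant in placenta, fell by 1.17 on the log2 scale in females, from 737 ± 123 to 335 ± 96.6 (SD, n = 4 each, limma adjusted p = 0.0320), and by 1.00 per dam (0.00381). In males its log2 fold change was -0.87 (0.412), and the difference between the sexes was 0.30 ± 0.39 (SE, limma adjusted p = 0.882). The identical unnamed genes ENSRNOG00000062337 and ENSRNOG00000065674 had a mean of 11072 ± 11815 in saline and 678 ± 259.9 in PolyI:C males, and of 6014 ± 5456 and 464 ± 77.8 in females, where the log2 fold change was -3.01 ± 0.72 (limma adjusted p = 0.0601). The yolk sac, amnion and epithelial list varied more widely between placentas than any other list, with mean log2 levels from 6.73 in saline female 1 to 11.7 in PolyI:C female 1.

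Cfap44 and Dynlrb2, both genes of cilia, were among the 10 largest falls in females, which raised the hypothesis that ciliated cells were more frequent in the saline samples. In a list of 47 cilia genes written for this test, 24 were measured, 17 with a negative and 7 with a positive change in females, and 3 passed in limma. The median log2 change was -0.38 in females, with an SD of 0.72 over the members, and -0.19 in males. With members on both sides of 0 and a spread of this size, the median does not decide, and the hypothesis stays open.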
